A study of Glycine max with 23 samples.

How the data were processed

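Soybean plants of 1 cultivar were grown at 22 °C with 16 h of light and 8 h of dark, per the labels' protocols. Pods of 1.3 to 2.0 cm held seeds with heart-stage embryos, which were fixed in ethanol and acetic acid, embedded in paraffin and cut at 8 µm before laser capture of 8 compartments (19 arrays). Whole seeds and leaves of 1.5 to 2.5 cm were ground in liquid nitrogen (4 arrays). For all 23 arrays 2 ng of total RNA was amplified and labelled with biotin, per the labels' protocols, while the extraction reagent differed between captured and ground samples. Endosperm replicate 3 was captured with a different microscope model.

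The deposited values are intensities on a linear scale, 1 per probe set and array, and GCOS 1.3 is named in the submitters' processing notes. The method that summarised the probes is not given in the sources used here. From the values, the mean over all 61170 probe sets after trimming 2% at each end was 500.05 to 500.07 on every array, so the deposited intensities share 1 scale and were not scaled again. A scaling to a fixed mean sets levels relative to the array's total, so a sample with fewer expressed genes shows those genes brighter.

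The comparisons used the 37593 soybean probe sets. The 23350 probe sets for the pathogens Phytophthora sojae (15820) and Heterodera glycines (7530) on the same array gave the background, the 95th percentile of their signal per array, and 227 control and rRNA probe sets were left out. A probe set was tested where it was above background on every array of at least 1 group (25686 probe sets). Signals were analysed as log2(signal + 16), so a fold is on that scale and understates the change of dim genes. One linear model of the 10 groups was fitted to all 23 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), leaving 13 residual degrees of freedom, and each comparison was a 2-sided contrast of group means with Benjamini-Hochberg adjustment over the tested probe sets. A probe set was called at an adjusted p under 0.05 and an estimate of at least 2-fold, and was compartment-specific at an adjusted p under 0.05 and at least 4-fold above each of the other 7 captured compartments. Errors of log2 fold changes are standard errors. Where a gene was below background on every array of the dimmer side, the fold is given as "at least", from the brighter side's mean against the background of the dimmer arrays or the probe set's own signal where that was higher. Where only some of the dimmer arrays were above background, the fold is an estimate against a level partly below it. The pathogen probe sets may cross-react, so background is an upper estimate.

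Genes were named from the platform annotation, which covered 9047 of the soybean probe sets, 8677 with 1 gene and 370 with several. The other 28546 are unnamed here. Of 6031 genes with a probe set of their own, 6010 were found by their gene ID in the RefSeq table of the assembly Glycine_max_v4.0, which was used for names only, and 1005 genes (1676 probe sets) had a symbol beyond a locus number. No coordinates are given. For the comparisons of embryo proper with suspensor, of endosperm, of the seed coat and of whole seed with leaf, the named genes were the 8 with the largest fold in each direction. They had to be called, to have 1 gene and an informative symbol, to be above background throughout a group of the higher side, to show no overlap between the sides and to be the brightest probe set of their gene. For each seed coat region the 5 highest and 2 lowest were taken, for specific probe sets the 4 with the widest margin per compartment, and for each list that passed its test up to 3 called members with the smallest adjusted p. Of 73 further probe sets for the named genes, 6 went the other way in at least 1 comparison. They are 1 each for CYP93E1, C4H, HSF-01, GSTU13, HIDH and LOXB1, and none of them was called there. Others kept the sign of the named probe set without being called, and not all of those are given below.

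Gene lists were tested with camera in limma, with a preset correlation of 0.01 and again with the correlation estimated from the data, on the brightest probe set per gene, for lists with at least 5 tested genes and with adjustment over the lists within a comparison. The 27 lists fixed before the data were examined matched gene descriptions, which the annotation used here lacks, so only 4 of them could be tested. A further 36 lists of gene symbols and transcription factor families were written after the annotation had been seen and before any comparison was computed, and 34 of them were tested. Unless said to be fixed in advance, a list named in the results is one of these 34. Over the 10 comparisons 35 of the tests of symbol lists were called, 11 of them also with an estimated correlation, and so were 3 of the tests of the lists fixed in advance. For embryo proper against suspensor, simulated arrays with 200 changed probe sets (no other differences, 24184 and 24170 probe sets tested) gave 39.0% of 4-fold and 83.0% of 8-fold changes back as called, with 0 and 15 false calls. For whole seed against leaf the shares were 23.0% and 62.5%, for hilum against the other coat regions 42.5% and 75.0%, and for seed coat against embryo and endosperm 85.0% and 93.0%. Of 2-fold changes 0% came back for embryo proper against suspensor and for whole seed against leaf, 1.5% for the hilum and 22% for the seed coat. The shares are of all 200 changed probe sets, of which 175 to 193 were tested. In the data many more probe sets differed (5934 of 25686 called between embryo proper and suspensor). That eases the Benjamini-Hochberg cutoff, so the simulated shares may understate recovery in the data.

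The design, the comparisons and the alternatives below were chosen before the data were examined. The alternatives were offsets of 1 and 64, quantile normalization, scaling to equal medians of detected probe sets, no filter, background at the 99th percentile, eBayes without a trend, the replicate number as a block, only the arrays of the groups compared, no probe sets shared between transcripts, no minimum fold, and leaving out each array in turn. Leaving out both arrays of highest background and limma's array weights were added once the array checks had been seen. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.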

Results

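Transcript levels were measured in soybean (Glycine max) seeds whose embryos were at the heart stage, with the Affymetrix Soybean Genome Array, a short-oligonucleotide array with 1 colour. The 23 arrays fell into 10 groups. Laser capture from 8 µm sections of fixed seeds gave the embryo proper, the suspensor (the stalk that joins the embryo to the maternal tissue) and the endosperm (3 arrays each), and 5 seed coat regions, namely endothelium, epidermis, hilum, inner integument and outer integument (2 arrays each). Ground whole seeds and young trifoliate leaves added 2 arrays each. The design asked which transcripts mark each part of the young seed. No count of molecules lies behind an array signal, so the number of arrays limits the precision. The labels call the replicates biological and do not tie them to single plants, so the p-values measure only the spread between these samples.

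Between 13378 and 23564 of the 37593 soybean probe sets were above background per array. Leaf (21835) and whole seed (20947) had the most probe sets above background on every array of the group, and suspensor (11650) and endosperm (12865) the fewest. Suspensor replicate 1 had a background of 420.1 signal units and endosperm replicate 1 had 404.9, against 86.3 to 231.4 on the others. These 2 arrays detected the fewest probe sets, 13378 and 14751. At least 1 captured compartment held 22742 probe sets above background on every array, 8198 of them (36%) in all 8 compartments and 2930 (12.9%) in exactly 1. Of the 22742, 1470 (6.5%) were below background on both whole seed arrays. Arrays of the same group correlated with a median r of 0.92 across soybean probe sets (log2 scale, range 0.793 to 0.961), and arrays of different groups with a median r of 0.809.

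**Figure D1:**
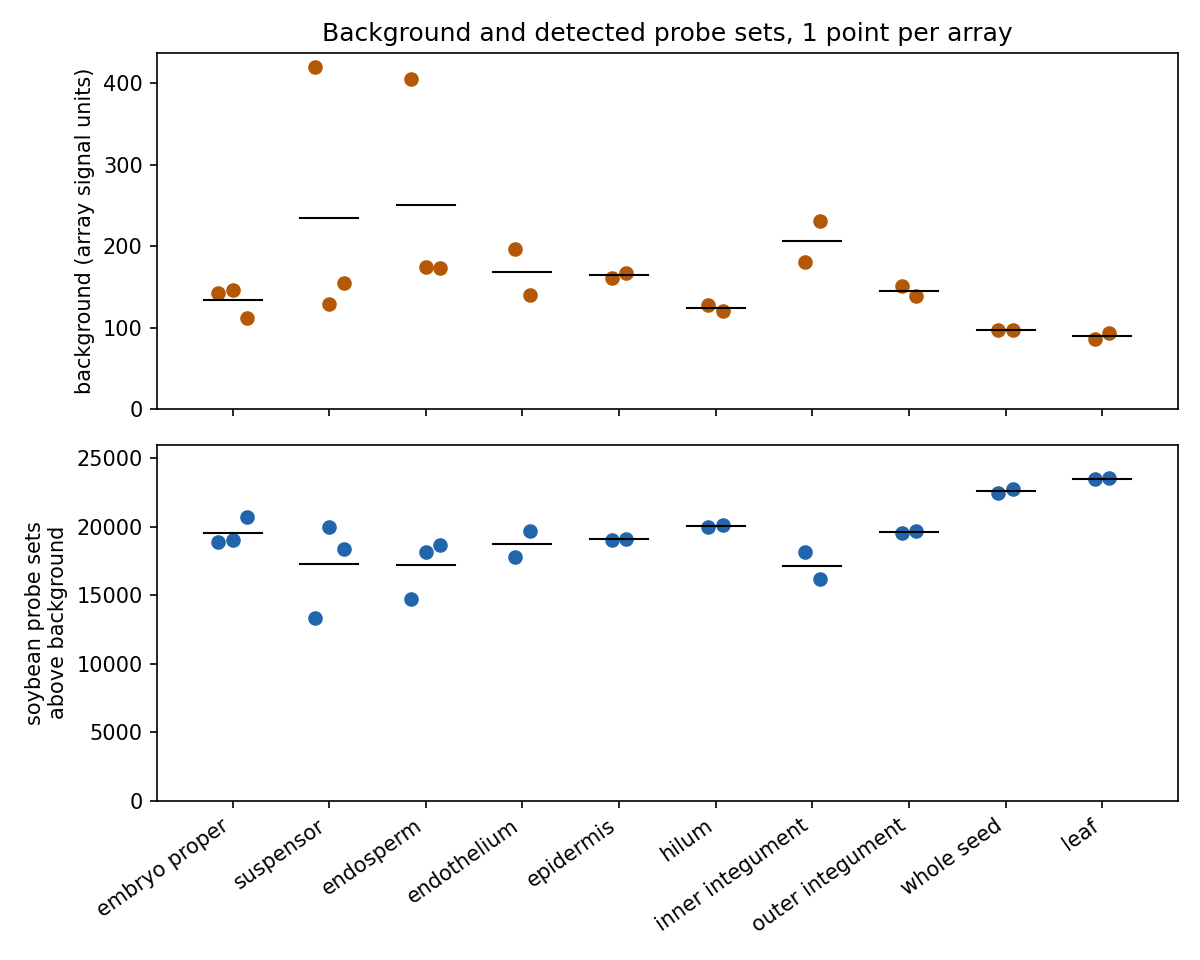
Background (upper panel, array signal units, 95th percentile of the pathogen probe sets) and number of soybean probe sets above it (lower panel), with 1 point per array and the group mean as a line. Suspensor replicate 1 (420.1) and endosperm replicate 1 (404.9) had the highest backgrounds and the fewest detected probe sets.

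The embryo proper was compared with the suspensor. Genes of the photosynthesis list were higher in the embryo proper, and those of the phenylpropanoid, flavonoid, isoflavonoid, WRKY and seed maturation lists in the suspensor. With an estimated correlation the photosynthesis call held and the 5 suspensor calls did not (adjusted p = 0.088 to 0.30). In the embryo proper, PHANa, a MYB factor of lateral organ development, was 40.5-fold higher (log2 fold change 5.34 ± 0.34 SE, adjusted p = 4.7e-10, n = 3 arrays per side), and the knotted-type homeobox gene H1 was 29.5-fold higher (4.88 ± 0.64, adjusted p = 6e-06). The triterpenoid gene CYP93E1 was at least 13.6-fold higher there, and the isoflavone glucosyltransferase gene IF7GT at least 14.4-fold. In the suspensor, the maturation protein genes PM9 (124-fold) and MP2 (92-fold), the transcription factor gene WRKY51 (109-fold), the polygalacturonase inhibitor gene PGIP (85.7-fold) and the lipoxygenase gene LOX3 (83.8-fold) were higher, all with adjusted p at or below 1.2e-07. CYP82A3 (at least 34.7-fold), GER2 (at least 41.3-fold) and H4 (373-fold) were higher in the suspensor too. LRK1 (38-fold), CYP28 (at least 5-fold) and CYP72A67 (at least 8.53-fold) were higher in the embryo proper. On the dimmer side H4, H1 and LRK1 were above background on 1 of 3 arrays, and PHANa and PGIP on 2. CYP93E1 has other probe sets at 2.21, −0.44 and 0.45 on the log2 scale (adjusted p = 0.011, 0.67 and 0.78). Another for CYP72A67 was at 1.35 (adjusted p = 0.22).

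Genes of the photosynthesis and chlorophyll list rose in the embryo proper, 8 of 14 with none fallen, a call that held with an estimated correlation (adjusted p = 0.00039, and 0.038 with an estimated correlation). They included ATPC, the gamma subunit of the chloroplast ATP synthase (at least 2.74-fold), and the Rubisco activase genes RCA11 (at least 2.60-fold) and RCAALPHA (10.1-fold). Of 9 tested phenylpropanoid and lignin genes, 6 were higher in the suspensor and none in the embryo proper (adjusted p = 0.004, adjusted p = 0.088 with an estimated correlation). C4H, which hydroxylates cinnamate, was 12.4-fold higher, the coumarate ligase gene 4CL3 at least 8.60-fold and CYP98A2 at least 16.8-fold. In the flavonoid list 7 of 15 genes were higher in the suspensor and 1 in the embryo proper (adjusted p = 0.024, adjusted p = 0.30 with an estimated correlation), with the chalcone isomerase genes CHI2-A (32.9-fold) and CHI1A (17.8-fold) and the hydroxylase gene F3H (57.5-fold) among them. The isoflavonoid list had 7 of 12 higher in the suspensor and 1 in the embryo proper (adjusted p = 0.032, adjusted p = 0.16 with an estimated correlation). Here chalcone reductase CHR5 was at least 32.2-fold and isoflavone synthase IFS2 at least 26.4-fold higher, and isoflavone reductase IFR2 5.54-fold. Of the WRKY factors, 16 of 37 were higher in the suspensor and 1 in the embryo proper (adjusted p = 0.00039, adjusted p = 0.16 with an estimated correlation). WRKY54 was 15.6-fold and WRKY19 at least 8.33-fold higher. In the embryo proper WRKY54 was above background on 1 of 3 arrays, and C4H and F3H on 2. Other probe sets for C4H (0.56, adjusted p = 0.56) and CYP98A2 (−0.47 and −1.28, adjusted p = 0.57 and 0.13) were not called. Further ones for CYP98A2 were called in the direction of the named one (−1.68, −3.29 and −4.96, adjusted p = 0.0068, 8.3e-05 and 1.2e-05). Of 20 seed maturation genes, 10 were higher in the suspensor and 1 in the embryo proper (adjusted p = 0.0026, adjusted p = 0.093 with an estimated correlation). Beside these suspensor groups stand the 8 genes named as highest in the seed coat, which had to be lower in the suspensor than in every coat region. Their suspensor signals, low in part through that choice, were 0.279% (PIP2-8), 0.613% (GASA6), 0.901% (GS-2), 1.51% (PIP2-4), 3.83% (SEP1), 4.7% (MADS28), 9.76% (GASA27) and 10.8% (AGL1L) of those in the richest coat region. Other abundant coat transcripts were chosen only against the embryo proper and endosperm. Their median suspensor share of the region's level ran from 8.59% (outer integument) to 18.3% (endothelium). AGL1L and GASA27 had 2130 ± 1280 and 3290 ± 1560 in the suspensor (SD, n = 3), against 63.5 ± 23 and 27.2 ± 30.8 in the embryo proper, while PIP2-8 and GS-2 had 143 ± 145 and 81.6 ± 34.2, against 246 ± 85.7 and 442 ± 143.

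In all, 5934 of 25686 tested probe sets were called, 3253 (54.8%) higher in the embryo proper and 2681 higher in the suspensor. Without suspensor replicate 1, the array of highest background, the flavonoid list (median log2 fold change −1.76 before and −1.47 after, adjusted p = 0.0547) and the isoflavonoid list (−1.86 and −1.75, adjusted p = 0.0674) lost their calls, and without embryo proper replicate 2 the isoflavonoid list did (−1.43, adjusted p = 0.0615). The isoflavonoid call was also lost with an offset of 1 (adjusted p = 0.088), with array weights (0.0675) and without both arrays of high background (0.0783). With each array scaled to the same median of its detected probe sets, 66.2% of the calls were higher in the embryo proper and the median over all probe sets moved from 0.07 to 0.30, so differences of that size depend on the scaling.

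Endosperm was compared with the mean of the embryo proper and the suspensor. A gene high in only 1 of these 2 regions can therefore appear lower in the endosperm. Genes of the seed maturation, photosynthesis, isoflavonoid, flavonoid, jasmonate and glutathione S-transferase lists were lower in the endosperm, and those of the protein folding and 14-3-3 lists were higher. None of these 8 calls held with an estimated correlation (adjusted p = 0.064 to 0.46). Among single genes, the cysteine synthesis gene OAS-TL2 was 16.2-fold higher (4.02 ± 0.60, adjusted p = 3.1e-05), the omega-3 fatty acid desaturase gene FAD3C 15-fold (3.91 ± 0.55, adjusted p = 1.6e-05), the glycosyltransferase gene UGT1 8-fold and the auxin influx carrier gene LAX11 7.96-fold. ERF5 (8.80-fold), MFT, a relative of the flowering gene FT (7.80-fold), HDL57 (8.85-fold) and SPK-1 (7.50-fold) were also higher. The fatty acid and lipid list (3 of 23 higher and 3 lower, adjusted p = 0.99, adjusted p = 0.99 with an estimated correlation) and the auxin list (3 of 9 higher and 2 lower, adjusted p = 0.95, adjusted p = 0.97 with an estimated correlation) were not called. On the other side MP2 was at least 19-fold lower, PM3 at least 26.5-fold, the gibberellin-regulated peptide gene GASA34 at least 34-fold, the chlorophyll breakdown gene SGR at least 24.6-fold and FWL5 at least 4.70-fold. GASA14 was 36.6-fold lower (−5.19 ± 0.30, adjusted p = 3.7e-11). GASA14 was above background on 2 of 3 endosperm arrays. Of the 6 embryo arrays, OAS-TL2 was above it on 1, ERF5, HDL57 and SPK-1 on 3, and FAD3C and MFT on 4. Another probe set for UGT1 was at 0 (adjusted p = 1).

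Of 20 seed maturation genes 11 fell in the endosperm and none rose (adjusted p = 0.0011, adjusted p = 0.064 with an estimated correlation), with PM16 35.9-fold lower and PM9 at least 14-fold. PM9 had a mean of 38800 in the suspensor and 303 in the embryo proper, and 396.1, 156.6 and 168.2 on the endosperm arrays. Its fold thus came from the suspensor. Of 14 photosynthesis genes 7 fell and 1 rose (adjusted p = 0.0016, adjusted p = 0.064 with an estimated correlation), RCA14 by 51.6-fold, RCAALPHA by 14.1-fold and ELIP, an early light-induced protein gene, by 15-fold. The isoflavonoid list had 8 of 12 lower and none higher (adjusted p = 0.019, adjusted p = 0.087 with an estimated correlation), among them the dehydratase gene HIDH (14.5-fold), IFR2 (5.79-fold) and CHR5 (at least 2.12-fold). For CHR5 the compartment next to the suspensor (4790 ± 627) was the endosperm (69.4 ± 59.1, below background), so its fold came from the suspensor. Of 15 flavonoid genes 5 fell and none rose (adjusted p = 0.046, adjusted p = 0.46 with an estimated correlation), with CHI1A 19.4-fold, CHI4A 15.4-fold and UGT78K1, an anthocyanidin glucosyltransferase gene, at least 13.9-fold lower. Among lipoxygenase and jasmonate genes 8 of 16 fell and 2 rose (adjusted p = 0.027, adjusted p = 0.085 with an estimated correlation). The allene oxide cyclase gene AOC3 was at least 6.73-fold lower and LOX3 12.0-fold. LOX3 stood at 14.71 on the log2 scale in the suspensor and at 8.33 in the embryo proper, so the suspensor set much of its fold. Glutathione S-transferases had 10 of 22 lower and none higher (adjusted p = 0.038, adjusted p = 0.36 with an estimated correlation), GSTU13 by 10.1-fold and GSTU41 by 4.24-fold. The heat shock and folding list had 5 of 13 higher and none lower (adjusted p = 0.042, adjusted p = 0.11 with an estimated correlation), among them the endoplasmic reticulum chaperone gene BIP4 (2.96-fold) and the disulfide isomerase gene PDIL-2 (3.18-fold). For 14-3-3 proteins 3 of 8 rose and none fell (adjusted p = 0.038, adjusted p = 0.38 with an estimated correlation), with SGF14f at 4.04-fold and GF14B at 2.63-fold. In the endosperm PM16, RCA14, RCAALPHA, CHI4A and LOX3 were above background on 1 of 3 arrays, and ELIP, HIDH, CHI1A and GSTU13 on 2. Other probe sets for HIDH (1.03, adjusted p = 0.27), GSTU13 (1.08, 0.29), GSTU41 (−0.06, 0.95) and IFR2 (−0.43, 0.69) were not called.

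The test called 4941 probe sets, 2285 higher and 2656 lower in the endosperm, and the median over all tested probe sets was 0.16 on the log2 scale, against which these changes are to be read. The flavonoid call was lost without endosperm replicate 2 (median −0.35, adjusted p = 0.296), embryo proper replicate 2 (0.0537) or suspensor replicate 1, 2 or 3 (0.0983, 0.0524 and 0.0537). The folding call was lost without endosperm replicate 1 or 2 (0.0734 and 0.0927) or suspensor replicate 1 or 2 (0.0738 and 0.0552), and without both arrays of high background (0.0648). The 14-3-3 call was lost without endosperm replicate 2 or 3 (0.0927 and 0.0699) or suspensor replicate 1 (0.0738), the glutathione S-transferase call without endosperm replicate 2 or 3 (0.0927 and 0.0516), and the jasmonate call without endosperm replicate 3 (0.0516) or suspensor replicate 1 (0.0529). Scaling to equal medians also ended the 14-3-3, flavonoid and glutathione S-transferase calls (0.0546, 0.0546 and 0.0508), and an offset of 1 the flavonoid call (0.0513).

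The seed coat, as the mean of its 5 regions, was set against the mean of embryo proper, suspensor and endosperm. Genes of the aquaporin list were higher in the coat, and those of the seed maturation and embryo regulator lists were lower. The seed maturation call held with an estimated correlation, and the aquaporin and embryo regulator calls did not (adjusted p = 0.096 and 0.11). The plasma membrane aquaporin gene PIP2-8 was 115-fold higher in the coat (6.85 ± 0.34, adjusted p = 1.8e-12, n = 10 coat arrays and 9 others) and PIP2-4 34.6-fold. GASA27 was 86.1-fold and GASA6 64-fold higher, and the MADS-box genes MADS28 (62.9-fold), AGL1L (55.2-fold) and SEP1 (21.6-fold) and the glutamine synthetase gene GS-2 (24.7-fold) were as well. The GASA peptide list, with 6 of 15 higher and 2 lower, was not called (adjusted p = 0.41, adjusted p = 0.61 with an estimated correlation). Lower in the coat were LEC1-A, a central regulator of embryo development (at least 26.9-fold), the maturation protein gene PM29 (at least 12.4-fold), SGR (at least 10.3-fold), the superoxide dismutase genes SODB2 (62.1-fold) and SODB (60.1-fold), SC-04 (80.6-fold), SC-03 (60.9-fold) and P89 (117-fold). P89 was above background on 1 of 10 coat arrays and SODB on 3. Of the 9 other arrays, SEP1 was above it on 2, MADS28 on 3, and AGL1L, GASA6 and GASA27 on 4.

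Of 20 aquaporin genes 9 rose in the coat and 1 fell (adjusted p = 0.0025, adjusted p = 0.096 with an estimated correlation), PIP2-6 by 11.6-fold. Of 20 seed maturation genes 15 were lower in the coat and 1 higher (adjusted p = 4.6e-06, adjusted p = 0.022 with an estimated correlation), with PM16 at least 10.5-fold and MP2 at least 4.74-fold lower. MP2 had 46600 ± 13400 in the suspensor and 496 ± 169 in the embryo proper (SD), and was below background on every endosperm array. Its fold thus came mostly from the suspensor. In the list of embryo and seed regulators, fixed in advance, 2 of 5 genes were lower over all genes tested, LEC1-A and WRI1B, a regulator of oil synthesis (20.7-fold, above background on 1 of 10 coat arrays), and 3 adjusted over the list alone (adjusted p = 0.033, adjusted p = 0.11 with an estimated correlation). Its call was lost without suspensor replicate 1 (median −0.83, adjusted p = 0.0683), without both arrays of high background (−0.63, 0.114), with array weights (0.0729) and with an offset of 1 (0.075). In total 5512 probe sets were called, 3097 higher and 2415 lower in the coat, and 9130 without the minimum fold.

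Each seed coat region was compared with the mean of the other 4, so that these comparisons share arrays and a gene high in one region lowers the contrast of the others. The endothelium, the innermost layer, stood out by phenylpropanoid genes. CYP98A2 was 54.4-fold (5.76 ± 0.62, adjusted p = 2.6e-06, n = 2 arrays against 8), 4CL3 24-fold and the reductase gene CCR 17.4-fold higher there. Of 9 genes of this list 6 rose and none fell (adjusted p = 2e-06, adjusted p = 0.0058 with an estimated correlation). H4 (125-fold), GSTIR (38.4-fold), GER2 (38.1-fold) and SARK (26.5-fold) were also higher. GSTU30 (17.1-fold) and NRT1-3 (14.1-fold) were lower, each above background on 1 of 2 endothelium arrays. Of the 8 other coat arrays, GSTIR was above it on 3 and SARK on 4. Other probe sets for CYP98A2 (0.96 and 0.98, adjusted p = 0.36 and 0.43), GSTIR (1.18, 0.42) and NRT1-3 (−1.08, 0.44) were not called. Further ones for CYP98A2 were called in the same direction (2.57, 4.45 and 5.94, adjusted p = 0.00038, 7.1e-06 and 4.1e-06). Of 16 lipoxygenase and jasmonate genes 3 fell and 1 rose (adjusted p = 0.023, adjusted p = 0.074 with an estimated correlation), including VLXB by 5.48-fold, and of 7 PHR factors, which regulate phosphate responses, 2 fell and none rose (adjusted p = 0.024, adjusted p = 0.42 with an estimated correlation), PHR24 by 5.21-fold. Of 1677 called probe sets, 911 were higher and 766 lower, and 531 were called without endothelium replicate 1. That array also decided the PHR list (adjusted p = 0.236 without it), GSTU30 (0.254), NRT1-3 (0.502) and the second PHR gene, PHR13 (0.455), and endothelium replicate 2 the jasmonate list (0.0902 without it).

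Flavonoid genes were higher in the epidermis, the outermost layer, and in the hilum, calls that were lost with an estimated correlation (adjusted p = 0.085 and 0.12). Of 15 flavonoid genes 9 rose and none fell in the epidermis (adjusted p = 1.1e-06, adjusted p = 0.085 with an estimated correlation). DFR1, a dihydroflavonol reductase gene of anthocyanin synthesis, was 23-fold higher (4.52 ± 0.68, adjusted p = 0.00014), CHI4A 21.7-fold, the anthocyanidin synthase gene ANS2 16.7-fold and CHI2-A 7.91-fold. SSH2 was 69.3-fold, ACS1 42.7-fold, HSF-01 28.3-fold and BZIP48 at least 6.33-fold higher, and FAD3C was 40.9-fold lower (above background on 1 of 2 epidermis arrays). Of the 8 other coat arrays, ACS1 was above it on 2 and SSH2 on 3. Another probe set for HSF-01 was at −0.49 (adjusted p = 0.64). The test called 2023 probe sets, 1055 higher and 968 lower, and 791 or 809 without epidermis replicate 1 or 2. In the hilum, the scar region through which the seed is supplied, 7 of 15 flavonoid genes rose and none fell (adjusted p = 0.00035, adjusted p = 0.12 with an estimated correlation). The anthocyanidin reductase gene ANR1, of proanthocyanidin synthesis, was 23.4-fold (4.55 ± 0.78, adjusted p = 0.00044) and ANS2 11.7-fold higher. The isoflavone conjugation genes IF7GT (81.2-fold) and IF7MaT (53.7-fold) and the MADS-box gene NMH7 (91.3-fold) were higher too, above background on 2, 2 and 4 of the 8 other coat arrays. Lower in the hilum were NOD33 (at least 12.8-fold), the phytosulfokine precursor gene PSK3 (70.2-fold) and the ferritin genes SFERH-2 (10.1-fold) and H-1 (6.99-fold, with another probe set at −0.30, adjusted p = 0.76). Of 7 iron storage and haem oxygenase genes 3 fell (adjusted p = 0.002, adjusted p = 0.033 with an estimated correlation), and of 14 photosynthesis genes 4 fell (adjusted p = 0.0013, adjusted p = 0.033 with an estimated correlation), RCAALPHA by 11.8-fold. None of either list rose. Of 2334 called probe sets 1110 (47.6%) were higher, and 57.7% after scaling to equal medians, and 824 or 827 were called without hilum replicate 1 or 2.

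Genes of the sugar transport list fixed in advance were higher in the inner integument than in the other coat regions. The sugar exporter gene SWEET13 was 26.6-fold (4.73 ± 0.59, adjusted p = 4.5e-06, n = 2 against 8), SWEET24 19.7-fold and SWEET34 16.9-fold higher there, and 4 of the 8 genes of the list rose, with none fallen, both over all genes tested and adjusted over the list alone (adjusted p = 0.00061, adjusted p = 0.022 with an estimated correlation). In the hilum 2 of the same 8 genes were lower, SWEET13 (at least 4.84-fold) and SWEET24 (9.77-fold), and 3 adjusted over the list alone (adjusted p = 0.048, adjusted p = 0.18 with an estimated correlation). That hilum list call was lost without any 1 of 6 arrays (adjusted p = 0.0572 to 0.0804 without endothelium replicate 1, epidermis replicate 2, hilum replicate 2, inner integument replicate 1 or 2, or outer integument replicate 2), with quantile normalization (0.0672) and with an offset of 1 (0.0702), and the 2 gene calls without hilum replicate 2 (SWEET13, 0.0506) and hilum replicate 1 (SWEET24, 0.156). A longer sugar transport list of 16 genes was called in neither region, with 5 higher and none lower in the inner integument (adjusted p = 0.058, adjusted p = 0.45 with an estimated correlation) and 3 lower and none higher in the hilum (adjusted p = 0.097, adjusted p = 0.26 with an estimated correlation). NOD33 was 134-fold higher in the inner integument, the cytosolic glutamine synthetase gene GS1-GAMMA 35.7-fold, FAD3C 35-fold and the auxin-induced gene AUX22 33.7-fold. CRK5 was at least 8.31-fold and HSF-01 48.7-fold lower. SWEET13 was above background on 3 of the 8 other coat arrays, and HSF-01 on 1 of 2 inner integument arrays, as was CHI4A. Another probe set for HSF-01 was at 0.88 here (adjusted p = 0.20). Flavonoid genes were lower, 7 of 15 with none higher (adjusted p = 0.014, adjusted p = 0.45 with an estimated correlation), CHI4A by 28.9-fold. Of 4837 called probe sets 1967 (40.7%) were higher, against 29.3% after scaling to equal medians, and 2589 were called without inner integument replicate 2.

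In the outer integument, genes of the lipoxygenase and jasmonate list were higher and those of the flavonoid and phenylpropanoid lists lower. Of 16 lipoxygenase and jasmonate genes 8 rose and none fell (adjusted p = 3.6e-06, adjusted p = 0.0031 with an estimated correlation), LOXB1 by 26.1-fold, VLXC by 25.2-fold and VLXB by 16.2-fold. Flavonoid genes had 9 of 15 lower (adjusted p = 3.2e-09, adjusted p = 0.013 with an estimated correlation) and phenylpropanoid genes 4 of 9 (adjusted p = 0.00022, adjusted p = 0.014 with an estimated correlation), with none higher in either, among them ANR1 (at least 14.7-fold), C4H (10.5-fold) and 4CL3 (at least 5.94-fold). The soyasaponin glycosyltransferase genes SGT2 (55.3-fold, 5.79 ± 0.56, adjusted p = 6.5e-07) and SGT3 (32.1-fold), CYP72A67 (44.9-fold), DRR1 (44.6-fold) and the proline-rich cell wall protein gene SBPRP (34.7-fold) were higher. Aquaporins had 5 of 20 higher and 1 lower (adjusted p = 0.018, adjusted p = 0.16 with an estimated correlation), with N-26, nodulin 26, at 5.95-fold. Of the 8 other coat arrays, DRR1 was above background on 2 and LOXB1 on 3. Other probe sets for LOXB1 (−0.64 and 1.39, adjusted p = 0.73 and 0.35), CYP72A67 (1.63, 0.27) and C4H (−1.65, 0.11) were not called. A further one for LOXB1 was called in the direction of the named one (2.70, adjusted p = 0.024). GER2 was at least 11.2-fold lower. The test called 1801 probe sets, 1049 higher and 752 lower, and 696 or 643 without outer integument replicate 1 or 2. Without replicate 2 the aquaporin list (median 0.80, adjusted p = 0.0869) and N-26 (adjusted p = 0.0665) lost their calls.

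Compartment-specific probe sets, higher in 1 captured compartment than in each of the other 7 by at least 4-fold, numbered 945. The suspensor had 344, the endosperm 160, the inner integument 113, the embryo proper 90, the outer integument 89, the endothelium 54, the epidermis 49 and the hilum 46. These counts do not rank the compartments by how distinct they are. The embryo proper, suspensor and endosperm had 3 arrays each and the coat regions 2. A probe set specific to a coat region also had to exceed the other 4 coat regions. PM9 had a suspensor signal of 38800 ± 2660 (SD, n = 3) against 303 ± 80.1 in the next compartment, the embryo proper, and MP2 one of 46600 ± 13400 against 496 ± 169. CHR5 was at least 19.3-fold and LOX3 53.6-fold above the next compartment. In the embryo proper, H1 (7770 ± 1460) was 29.5-fold, the late embryogenesis gene LEA5 (1170 ± 447) 14.1-fold, GPA1, encoding a G protein alpha subunit, 5.11-fold and PHANa 4.48-fold above the next compartment. The only named endosperm gene was CDPK-BETA, at least 3.37-fold above the suspensor. SSH2 led in the epidermis (23.5-fold), NMH7 in the hilum (27-fold) and VLXC (17.2-fold), SGT2 (11.5-fold), CYP72A67 (9.15-fold) and PIB1 (at least 4.70-fold) in the outer integument. BZIP48 (epidermis, at least 4.44-fold), BMY2 (6.01-fold) and GLYI-6 (5.74-fold, both inner integument) completed the named genes. In the inner integument SWEET34 (8190 ± 1850, n = 2) was 9.93-fold and NOD33 (38300 ± 5820) 9.74-fold above the next compartment. In the endothelium CYP98A2 (5.42-fold), CCR (4.75-fold), 4CL3 (4.24-fold) and WRKY32 (6.52-fold) met the rule, and all 4 lost it without endothelium replicate 1 (log2 margins 2.17, 1.91, 1.58 and 2.41, at least 1 adjusted p of the 7 or the margin then failing). Of the 945, 173 (18.3%) were below background on both whole seed arrays, 102 of them from the suspensor and 30 from the embryo proper. For MP2 the whole seed signal was 27.5 and for LEA5 49.2.

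Several of these specific calls were lost when 1 array was left out, not always with a smaller margin. Without endothelium replicate 2 the margins of CYP98A2, CCR and WRKY32 were 2.70, 2.58 and 3.00, against 2.44, 2.25 and 2.71 with all arrays. Without endosperm replicate 2 those of CCR and 4CL3 stayed at 2.25 and 2.08. In these cases an adjusted p failed and the 4-fold margin did not. CYP98A2 was also lost without endothelium replicate 2 (margin 2.70) or suspensor replicate 3 (2.20), and 4CL3 without embryo proper replicate 1 or 2, endosperm replicate 2, epidermis replicate 2 or outer integument replicate 1 or 2 (1.31 to 2.08). CCR was lost without embryo proper replicate 1, suspensor replicate 1, endosperm replicate 2, endothelium replicate 2 or either replicate of the epidermis, hilum or outer integument (1.54 to 2.58), and WRKY32 without endothelium replicate 2 or either replicate of the epidermis, hilum or inner integument (2.34 to 3.00). PHANa was lost without endosperm replicate 1 (1.84), GPA1 without epidermis replicate 1 (2.20) or hilum replicate 1 (2.35), CDPK-BETA without suspensor replicate 2 (1.82), epidermis replicate 2 (2.15) or endosperm replicate 3 (1.66), and PIB1 without endothelium replicate 1 (3.20). BZIP48 was lost without epidermis replicate 2 (3.34) or hilum replicate 1 (3.50), BMY2 without endothelium replicate 1 or 2 (2.59 each) or inner integument replicate 1 (1.21), and GLYI-6 without endothelium replicate 2, inner integument replicate 1 or 2, or outer integument replicate 1 or 2 (2.14 to 2.90). Processing settings ended some of the same calls. With an offset of 1, WRKY32, CCR, 4CL3, BZIP48, BMY2 and GLYI-6 were lost (2.1 to 3.74), with array weights PHANa, CYP98A2, CCR, WRKY32, BMY2 and GLYI-6 (1.74 to 2.90), and with no filter WRKY32, CCR, 4CL3 and GLYI-6 (2.08 to 2.71). CCR, 4CL3 and GLYI-6 were lost with only the arrays compared (2.08 to 2.52), CCR and 4CL3 without a trend (2.25 and 2.08), CCR and GLYI-6 with equal medians (2.08 and 2.30), CCR and PHANa without both arrays of high background (1.54 and 1.84), 4CL3 with quantile normalization (2.08) and CDPK-BETA with an offset of 64 (1.87). Among the counts, the endothelium had 25 without its replicate 1. The epidermis had 22 or 28 without its replicate 1 or 2 and 31 without hilum replicate 1. The hilum had 13 or 14 without its replicate 1 or 2 and 12 without endothelium replicate 1. The inner integument had 49 without its replicate 2 and 53 without endothelium replicate 2, and the outer integument 47 without either of its replicates and 59 without epidermis replicate 1. With an offset of 1 the hilum had 24, the epidermis 28, the inner integument 73 and the outer integument 59, and with array weights the hilum 75 and the inner integument 67. Without the minimum fold the suspensor had 554, the endosperm 278, the inner integument 211 and the embryo proper 153.

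**Figure D2:**
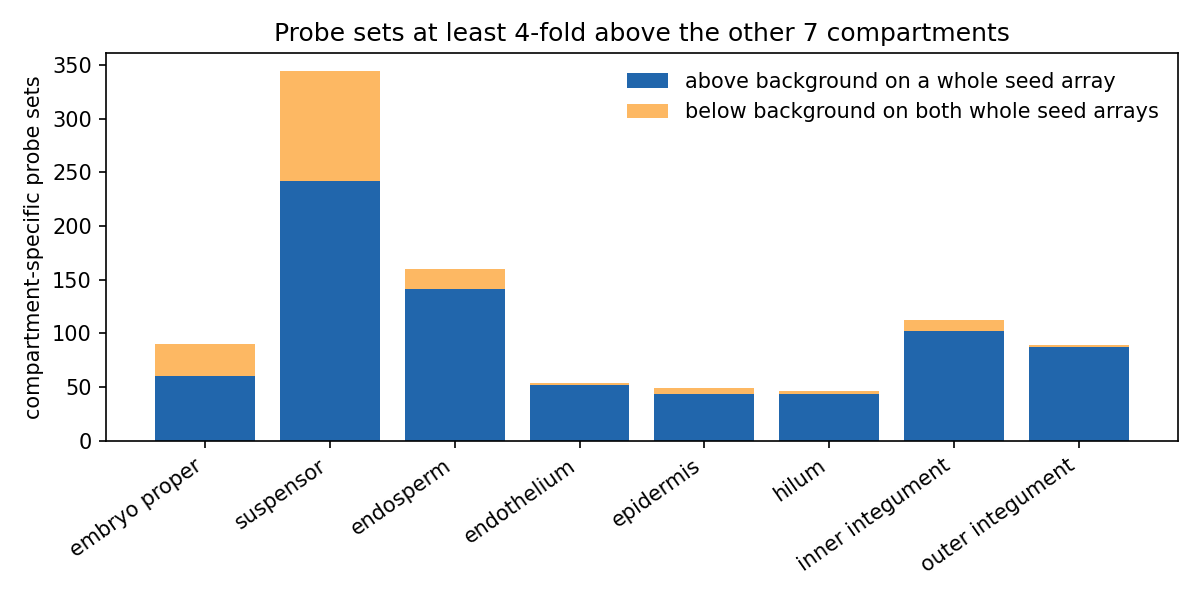
Number of compartment-specific probe sets in the 8 captured compartments (bar height, probe sets), split by whether the probe set was below background on both whole seed arrays (orange) or not (blue). The suspensor had 344, of which 102 were below background in whole seed, and the hilum 46, of which 2 were.

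**Figure D3:**
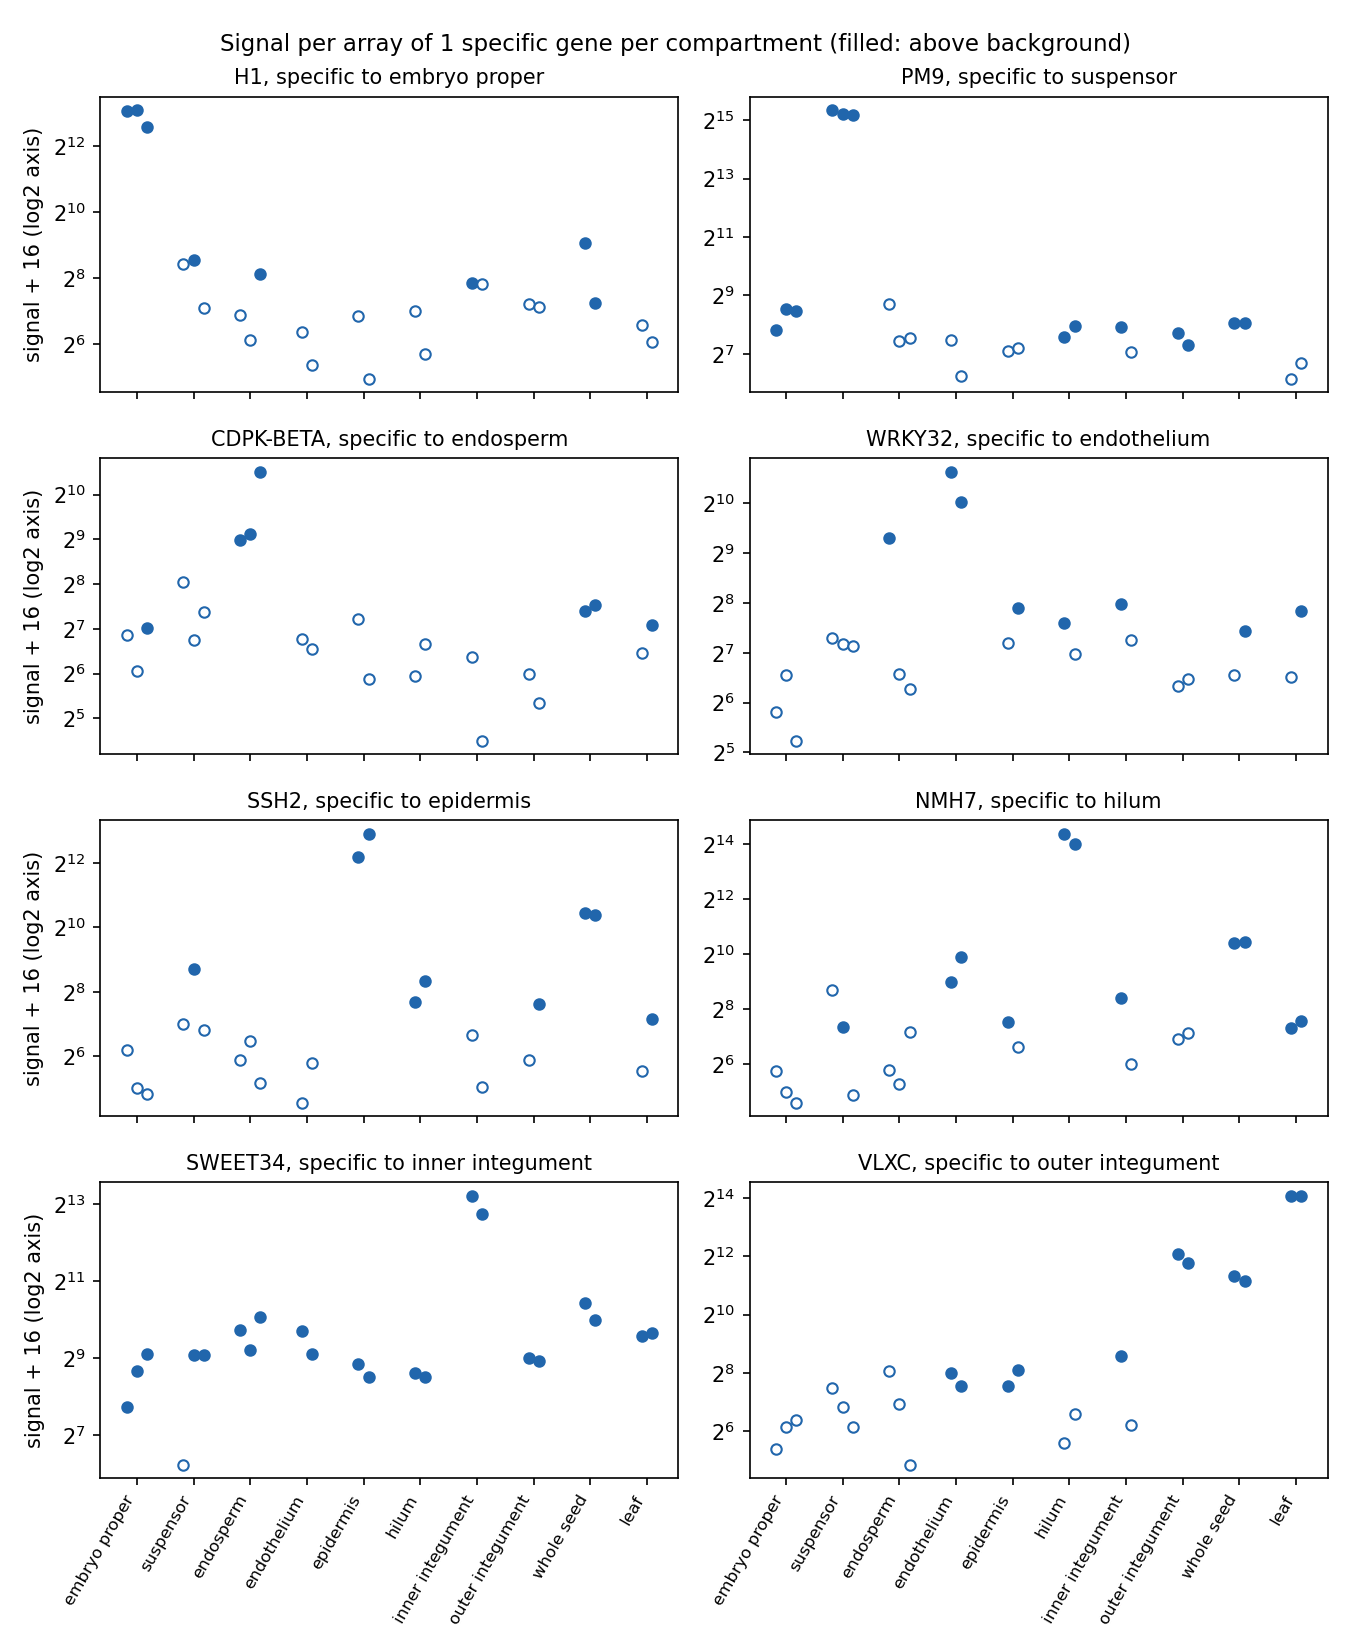
Signal per array plus the offset of 16 (log2 axis, array signal units) of the gene with the widest margin in each captured compartment, over the 10 groups, with 1 point per array. Filled points were above the array's background and open points were not, and PM9 reached 38800 on average in the suspensor against 303 in the embryo proper.

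Whole seed and leaf were both ground and extracted with the same reagent. Of 14 photosynthesis genes 10 were lower in whole seed and none higher (adjusted p = 1.6e-06, adjusted p = 0.0044 with an estimated correlation), ELIP by 22.7-fold, ATPC by 19.2-fold and RCA14 by 7.48-fold. Among the single genes higher there, SCB1, a seed coat BURP-domain protein gene, was at least 490-fold above leaf (adjusted p = 2.6e-09, n = 2 arrays per side), the MADS-box genes AGL1L and MADS28 at least 141-fold and 68.3-fold, ANR1 at least 211-fold, DFR1 at least 134-fold, ANS2 87.9-fold, the sugar exporter gene SWEET24 at least 77.8-fold and SC-04 82.1-fold. The flavonoid list was not called, with 5 of 15 higher and 3 lower in whole seed (adjusted p = 0.51, adjusted p = 0.72 with an estimated correlation). Higher in leaf were AG1 (at least 76.6-fold), CYP83E8 (at least 52.9-fold), FBA (at least 49.5-fold), INR2 (at least 28.5-fold), SIP1-6 (at least 23.1-fold), NES (at least 13.5-fold), ALDH2B4 (77.8-fold) and FWL5 (70-fold). On the dimmer side SC-04 and FWL5 were above background on 1 of 2 arrays. The test called 3385 probe sets, 1322 higher and 2063 lower in whole seed, with a median of 0.12 over all probe sets. It called 2064 or 1674 without whole seed replicate 1 or 2 and 1982 or 1830 without leaf replicate 1 or 2, and 6778 when only the 4 arrays compared were fitted.

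Whole seed was last compared with the mean of the 8 captured compartments, a contrast in which fixation, capture and the extraction kit differ along with the tissue. Genes of the lipoxygenase, cell wall protein, flavonoid, GASA peptide and aquaporin lists were higher in whole seed and those of the seed maturation list lower. The lipoxygenase and cell wall protein calls held with an estimated correlation and the other 4 did not (adjusted p = 0.084 to 0.15). SBPRP was higher by 19.3-fold (4.27 ± 0.35, adjusted p = 2.2e-07), PRP3 by 4.49 on the log2 scale, GASA29 15.1-fold, LOXB1 14.8-fold, VLXB 12.4-fold, ANR1 31.4-fold and N-26 10.6-fold, the last above background on 9 of 19 captured arrays. Other probe sets for LOXB1 were at 0.89, 0.24 and 1.91 (adjusted p = 0.44, 0.84 and 0.078), none of them called. Of 16 lipoxygenase and jasmonate genes 9 rose and 1 fell (adjusted p = 6e-05, adjusted p = 0.0083 with an estimated correlation), and of 12 cell wall protein genes 6 rose and none fell (adjusted p = 0.0036, adjusted p = 0.044 with an estimated correlation). The flavonoid (8 of 15 rose), GASA peptide (7 of 15) and aquaporin lists (6 of 20) had none fallen, with adjusted p = 6e-05, 0.00051 and 0.020, and adjusted p = 0.084, 0.084 and 0.15 with an estimated correlation. Seed maturation genes were lower as a list, with 2 of 20 fallen and 1 risen (adjusted p = 0.020, adjusted p = 0.15 with an estimated correlation). That list call was lost without whole seed replicate 1 (adjusted p = 0.133) and with quantile normalization (0.0841). The 2 that fell, MP2 (at least 1.05-fold) and PM31 (at least 2.16-fold), lost their calls without whole seed replicate 1 (0.626 and 0.369) or 2 (0.0573 and 0.243), and PM31 also without embryo proper replicate 2 or replicate 1 of the endothelium, epidermis, hilum or outer integument (0.0508 to 0.0571). MP2 was also lost with an offset of 1 (0.0916) and no filter (0.0559), and PM31 with equal medians (0.0531) and no filter (0.0574). PRP3 was not called without whole seed replicate 1 (0.0685) or 2 (0.0633). Of 2486 called probe sets 1785 (71.8%) were higher in whole seed, against 89.0% after scaling to equal medians, which moved the median over all probe sets from 0.10 to 0.39. Without whole seed replicate 1 or 2, 533 or 301 were called.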

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

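Both tests of the pathogen probe sets were chosen after the result was seen. Signal appeared in probe sets that none of the comparisons used. Of 23350 probe sets for Phytophthora sojae and Heterodera glycines, 2 were above the median detected soybean signal throughout at least 1 captured compartment and below background on every whole seed and leaf array. They carry the same Heterodera glycines identifier with different suffixes, so they are not independent. The first had mean signals of 1746.7 in the suspensor, 1380.3 in the inner integument and 853.5 in the epidermis, against 11.4 in whole seed and 10.4 in leaf, and was above background on 13 of 19 captured arrays (log2 difference 3.66, adjusted p = 3.28e-05 by limma). The other had 2497.9, 1218.2 and 792.3, against 10.9 and 15.1, and was above background on 14 of 19 (3.69, adjusted p = 0.000386). In the other captured compartments the 2 had 591.3 and 710 (endothelium), 361.1 and 504.6 (outer integument), 151.3 and 181.2 (hilum), 88.5 and 68.6 (embryo proper) and 40.4 and 133.8 (endosperm). Among all pathogen probe sets 14 were higher in the captured samples by limma and none lower.

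Infected or infested tissue would also have brought pathogen housekeeping transcripts, and the array's actin and glyceraldehyde-3-phosphate dehydrogenase controls for the pathogens were above background on 0 of 19 captured arrays, which argues against it. A by-product of fixing, sectioning and capturing tissue may be the source, since the captured samples share these steps. The larger number of compartments with such a probe set above background on every array was 6 of 8, short of the 7 that this source was taken to need, and the endosperm and embryo proper, fixed and captured alike, had far lower signal than the suspensor, so this source stays undecided. Preparation and sample type cannot be told apart here, because every captured sample was fixed and neither whole seed nor leaf was. Infection apart, no biological explanation was tested.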

How the results depend on the processing

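The array weights and the settings without the 2 arrays of highest background were chosen after the data had been seen. No called gene or list of the results changed direction under any alternative that was run. The share of hilum calls that were higher turned from 47.6% to 57.7% with equal medians. With no filter, which adds undetected probe sets, the median log2 difference over all tested probe sets changed sign for embryo proper against suspensor (0.07 to −0.10), the hilum (0.04 to −0.07), the inner integument (−0.05 to 0.05), the outer integument (0.033 to −0.002) and whole seed against the captured compartments (0.10 to −0.08). It also did for the seed coat (−0.027 to 0.031 with equal medians, 0.014 with only the arrays compared and 0.005 with background at the 99th percentile) and the endothelium (−0.012 to 0.001 with an offset of 1). Without a minimum fold, 9130 probe sets were called between the seed coat and the embryo and endosperm and 1486 were compartment-specific, since that setting drops a criterion. With only the arrays of the 2 groups compared, 6778 were called between whole seed and leaf. With the correlation estimated from the data, 11 of the 35 list calls held. Array weights gave 4289 called probe sets for the hilum, 3266 for the outer integument, 7030 for whole seed against leaf and 5869 for whole seed against the captured compartments. Apart from the minimum fold, the cause was not tested. Leaving out 1 array at a time gave 779 to 1087 specific and 22742 to 23670 detected probe sets, 31 to 40 list calls, and called counts of 4735 to 6375 for embryo proper against suspensor, 4062 to 5731 for the endosperm, 5343 to 5853 for the seed coat, 531 to 1790 for the endothelium, 791 to 2186 for the epidermis, 824 to 2621 for the hilum, 2589 to 4815 for the inner integument, 643 to 1950 for the outer integument, 1674 to 2064 for whole seed against leaf and 301 to 3089 for whole seed against the captured compartments. In a group of 2 arrays this left 1 array, assumed to vary like the other groups. Signal over background limits what could be compared. The suspensor (11650) and the endosperm (12865), each with 1 array of high background, had the fewest probe sets above it on every array, while the mean per array was 17248, 17195 and, in the inner integument, 17156. Without the 2 arrays of highest background, 6370 probe sets were called between embryo proper and suspensor, 5110 for the endosperm, 6076 for the seed coat and 1143 were specific. The labels do not say whether samples with the same replicate number are paired. The mean correlation of deviations between same-numbered arrays ran from −0.123 to 0.166 over 45 pairs of groups and exceeded 0.1 in 3. These were suspensor with endosperm (0.263, 0.097 and 0.138 in replicates 1, 2 and 3), embryo proper with endosperm (0.122, 0.02 and 0.221) and whole seed with leaf (0.138). Pairing within these groups is thus not excluded. With the replicate number as a block, 6162, 5144 and 5522 probe sets were called in the first 3 comparisons, 1768, 2168, 2449, 4986 and 1875 for the endothelium, epidermis, hilum, inner and outer integument, and 3572 and 3079 for whole seed against leaf and against the captured compartments. The block gave 36 list calls, and the hilum sugar transport list was not among them (adjusted p = 0.0543).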

Other observations

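The tests of the suspensor genes were chosen after the result was seen, except the first form of the seed coat test, and so were the tests of preparation, of the fitted tissue weights and of splits of whole compartments. The embryo regulator LEC1-A had a signal of 11500 ± 2480 in the suspensor, 4940 ± 515 in the embryo proper and 1850 ± 257 in the endosperm (SD, n = 3 each), and was below background on every seed coat array. The maturation gene PM16 had 9040 ± 1700 in the embryo proper and 4250 ± 1310 in the suspensor, and 171 ± 91.9 in the endosperm, while PM37 lay between 23700 and 33900 in all 8 captured compartments. The sugar exporter gene SWEET24 had 62100 ± 16200 in the inner integument, 25800 ± 2480 in the outer integument (n = 2 each) and 16200 ± 12600 in the suspensor, and 9.05 ± 2.76 in leaf, below background. SEOF had 958 ± 81.9 in whole seed and 2610 ± 825 in leaf, and at most 144 in a captured compartment. These genes were picked after their values were seen.

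In the suspensor, 20 phenylpropanoid, flavonoid and isoflavonoid genes were called higher than in the embryo proper, and 4 forms of a test for seed coat cells in the suspensor sections were run on them, the last 3 written after an earlier value was known. The first met the bound set against such cells, as the 351 probe sets specific to a seed coat region differed by a median of 0.31 between suspensor and embryo proper against 3.68 for the members, but those probe sets had been chosen as low in the suspensor, so that bound was wrong and the value decides nothing. In the other forms the members' median lay above 86.3% of 2515 other seed coat transcripts, and 14 of 20 members exceeded the signal that the seed coat share of other transcripts would give, while 6 of 20 were higher than in each seed coat region, none of which decided. Without suspensor replicate 1, the array of high background, the members had a median of 104% of their log2 difference left (85.5% to 127%), which argues against that array as the source, and 17 of 20 stayed called, while 4CL4 (−1.67 ± 0.54 SE before and −1.61 ± 0.60 after), IFS1 (−1.79 ± 0.62 and −1.85 ± 0.69) and IF7MaT (−1.92 ± 0.68 and −1.64 ± 0.76) lost their calls with the larger error of fewer arrays and, for 4CL4 and IF7MaT, a smaller difference. The members were divided by list after it had been seen which of them exceeded the seed coat, so the division itself decides nothing. Of 7 isoflavonoid genes, 4 (IF7MaT, IFS1, IFS2 and CHR5) were higher than in each region, which argues against seed coat cells as the whole source of those 4. All 7 exceeded that share, IFR2 with 6706 against 5564. IFR2, HIDH and IFR1 were not above each region and stay open (5 of the 7 still called without that array, 98.4% left). Of 13 phenylpropanoid and flavonoid genes, 2 were higher than in each region and 7 exceeded that share, which left seed coat cells open (12 still called, 111% left).

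For the 10 seed maturation genes higher in the suspensor, 9 stayed called without suspensor replicate 1, with a median of 100.1% of the difference left. That argues against this array as the source. Higher than in each seed coat region were 7, which argues against seed coat cells as the whole source of those 7. PM31, PM1 and PM27 were not above each region, so for them seed coat cells stay open. PM27 lost its call, at −1.59 ± 0.55 before and −1.43 ± 0.61 after.

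More probe sets were higher than lower in whole seed against the captured compartments, 1785 against 701. In 86.3% of those 1785, the highest captured compartment lay no more than 2-fold below whole seed. Unequal tissue masses would give this when 8 compartments are weighted alike, but so would any mix of the compartments. The value therefore does not show unequal masses. A mean of log2 values also lies at or below the log2 of an equal mix, so the excess could arise with equal masses too. Transcripts lowered by preparation, or from tissue that was not captured, stay open, since 2.0% exceeded every compartment by limma and 13.7% did so by more than 2-fold in the means, and 2 whole seed arrays leave little power for the first. The wording of this explanation was corrected after its value was known. The 35 probe sets above each compartment included those of BZIP16, SEOF and CEL12. A fit of whole seed as a weighted sum of the compartments gave the outer integument and hilum 89.2% of the weights together. With 1 array left out they had 83.4% to 92.0%, and the relative residual of the full fit was 0.337. These weights are not shown to be shares of the seed's RNA, since single specific genes did not follow them. NMH7 had 18900 in the hilum (weight 0.31) and 1350 in whole seed. SSH2 had 6200 in the epidermis (weight 0) and 1360, and VLXC 3920 in the outer integument (weight 0.32) and 2400.

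For embryo proper against suspensor, the real split of the arrays gave 4251 called probe sets in a fit of those arrays and the highest other 0, the real one being 1 of 10 splits, too few for a share under 0.05. For the endosperm 3 of 84 splits were at or above the real 1459, and the other 2 set the suspensor (2317) and the embryo proper (1460) apart from the rest, a structure of the samples. Splits that part replicates called almost nothing, so this argues against a random drawing of arrays. It says nothing of which compartment stands apart, as all 3 splits of whole compartments reached the real count and 3 are too few for a share under 0.05. For the seed coat the real split gave 3292, the highest other of 100 splits of arrays gave 8, and 1 split, the real one, was as large. Among the 56 splits of the 8 whole compartments the highest other gave 2095 and 1 was as large, though the real split is the most even in arrays. With replicates 1 and 2 of each compartment, so that every split has the same sizes, the real split gave 2540 and the highest other 1452. Only 1 of 56 was as large, the smallest share this test could give. That argues against chance but does not exclude it, as this form was chosen after the result was seen.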
